A study of Mus musculus with 2 samples.

How the data were processed

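Spleens of 2 pups of the same pregnancy were taken at postnatal day 0, and total RNA was sequenced with 1 library per spleen, per the labels. The labels name mirVana extraction, RNA longer than 200 nt, 10 ng of input and spike-ins, and list the manual of a low-input SMARTer cDNA kit among the protocols. Both samples carry the same donor identifier, while their descriptions name separate pups, and they were treated as separate animals of 1 litter. The replicate numbers come from the labels.

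For each library the authors deposited a gene table and a transcript table on mm10, per the labels, with GENCODE M4 gene models, per the text listing deposited with each sample. The column layout is that of RSEM. The aligner and the software versions are not given in the sources used here. The deposited expected counts are estimated counts, which need not be whole because reads that match several features are divided among them. The deposited TPM values are relative to all features, spike-ins included, and the effective length equals the length minus 99 nt in the genes with 1 transcript, so TPM of features barely longer than that is inflated. Posterior mean TPM and posterior SDs of counts were deposited by the authors as well. Whether counting used strand is not given in the sources used here, so overlapping and antisense genes may share reads.

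The tables hold 43346 Ensembl genes, 97 spike-ins and a class of numbered short features with a median length of 73 nt. Gene names, classes and coordinates came from GENCODE M21, also on GRCm38 (mm10), matched by Ensembl identifier: 42462 genes matched. The 884 that did not held 0.202% and 0.217% of counts in replicates 1 and 2. Where a symbol was on more than 1 identifier, which held for 20 symbols, the identifier with the higher mean count was used. Library totals were 33122187 and 32162543 estimated counts.

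Levels are the deposited TPM, with the mean and SD of 2 libraries. A gene counted as detected at 1 TPM in both. For differences, expected counts were rounded and scaled by TMM in edgeR 4.0.16 (R 4.3.3), and log2 CPM values were computed with a prior count of 2. Genes with a mean count of at least 20 entered. Spike-ins and numbered features were left out of library sizes. The common dispersion was estimated by edgeR with an intercept-only model. A list's median log2 ratio was placed among 10000 random lists of the same size drawn from 20 bins of mean log2 CPM. A list needed 3 members, and a median outside the central 95% was called standing apart, as a description of these libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest, and DESeq2 1.42.0 for an alternative scaling.

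The 38 gene lists, the thresholds, the scaling, the rule for named genes and all alternatives but the 4 named in the closing section as chosen after seeing the data were chosen before the data were examined. The rule takes the 20 genes with the highest mean TPM, the 3 highest members of every list, all members of small lists and of the globin and antigen receptor constant lists, and the number of members detected. For differences it takes the 10 protein-coding genes with the largest ratio in each direction at a mean count of at least 100, and the 3 members with the largest ratio in each list that stood apart. Ins1, Ins2, Hp, Trf, Fcer1a, Ccl21a, Itgax, Clec9a, Siglech, Zbtb46 and mt-Co3 are named with ratios or levels beyond that rule, chosen after their values were seen. The level of 1 gene that the rule takes is not reported here. List symbols without a match, such as Hbb-b1, Ahsp and Trdc, were not analysed here.

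The steps were tested on simulated counts for replicate 1 against replicate 2. With no changed gene a simulated coefficient of variation of 0.1 was estimated as 0.0996, and with 200 changed genes as 0.136, so genes that differ raise the estimate. Over 15509 genes, the median log2 ratio of 100 genes changed 2-fold was 0.98 and of 100 changed 4-fold 1.99. Of genes changed 4-fold 100% were at least 2-fold apart, of those changed 2-fold 47%, and 42 unchanged genes were too. Of 200 unchanged lists of 12 genes 2.5% lay outside the percentile range, and of 50 lists changed 2-fold 100% did. Genes were simulated as independent of each other, which members of a cell-type list need not be.

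Alternatives tried were posterior mean TPM, shares of counts, TPM rescaled to protein-coding genes or without spike-ins, other detection thresholds, other scalings (DESeq2 size factors, spike-in totals, library size, deposited TPM), other filters and prior counts, unmatched random lists, and each library alone. Intervals and limits for 0 counts cover counting error only, since reads without molecular identifiers are not independent molecules.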

Results

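Total RNA from the spleens of 2 newborn mice (0 days after birth, from the same pregnancy) was sequenced, with 1 library per pup. The libraries form 1 group, P0 spleen, with n = 2. Replicate 1 is the spleen of pup 2 and replicate 2 the spleen of pup 1. The estimated counts summed to 33122187 in replicate 1 and 32162543 in replicate 2. With 1 group the design holds no contrast between conditions. The data describe which genes the newborn spleen expressed, at what level, and how far 2 littermates differed. Unless stated otherwise, levels are TPM, transcript abundance normalized for length and library total, as mean ± SD over the 2 libraries (n = 2). Coordinates are on mm10.

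Adult globin transcripts dominated the newborn spleen. The 4 measured adult globin genes together held 26.7% ± 1.45 of all TPM. Hba-a2, an alpha globin gene (chromosome 11, 32296489 to 32297298), stood at 108047 ± 6333 TPM, and its near-identical copy Hba-a1 (chromosome 11, 32283511 to 32284465) at 52253 ± 2987. The beta globin genes Hbb-bs (chromosome 7, 103826534 to 103828096) and Hbb-bt (chromosome 7, 103812524 to 103813996) stood at 67961 ± 2109 and 38976 ± 3100. Reads shared within each pair of copies make the split between copies less certain than the sums. Alpha globin TPM was 1.51 times beta globin TPM in replicate 1 and 1.49 times in replicate 2. As a share of the estimated counts, which are not normalized for length, the adult globins held 12.5%.

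Embryonic globins, the haemoglobin chains of primitive erythroid cells, were expressed at low levels. Their summed TPM was 0.00238% ± 0.000513 of that of the adult globins. Hbb-y stood at 2.44 ± 0.0990 TPM, Hba-x at 2.43 ± 0.552 and Hbb-bh1 at 1.37 ± 0.368. Hbb-bh2 stood at 0.095 ± 0.00707 TPM, from a mean of 1 count, and Hbb-bh0 had 0 counts in both libraries. A count of 0 allows up to 3 counts, which is 0.0906 CPM (library-scaled counts) in replicate 1 and 0.0933 CPM in replicate 2. These limits cover counting error only.

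Erythroid genes other than globins were all expressed. Each of the 19 matched members reached 1 TPM in both libraries, and together they held 0.499% ± 0.0467 of TPM. Alas2, the first enzyme of haem synthesis in erythroid cells, stood at 713 ± 4.48 TPM. Mt2, a metallothionein, followed at 496 ± 28.2 and Slc4a1, the band 3 anion exchanger of red cells, at 475 ± 45.5. All 8 regulators linked to globin switching were above 1 TPM, led by Klf1 at 317 ± 52.0, Zbtb7a at 51.2 ± 0.0495 and Myb at 31.6 ± 0.163. The proliferation list was expressed in full as well, 16 of 16 members, with Rrm2, a subunit of ribonucleotide reductase, at 522 ± 117 TPM, Birc5 at 472 ± 69.9 and the replication clamp Pcna at 367 ± 58.3.

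After the adult globins, the late neutrophil granule list, which also holds other late neutrophil genes, took the largest share of TPM among the cell-type lists. The 13 late granule genes held 1.74% ± 0.429 of TPM, and the 8 early granule genes 0.108% ± 0.0236. By share of estimated counts the order was different, with 0.987% for the erythroid list and 0.745% and 0.139% for the late and early granule lists. All 21 reached 1 TPM in both libraries. S100a8 and S100a9, the subunits of calprotectin, stood at 8898 ± 2272 and 4676 ± 1185 TPM, and Retnlg at 1132 ± 145. S100a8 and S100a9 made up most of the late list's summed 17361 ± 4290 TPM, so its rank by TPM rests largely on them. Among early granule genes, Mpo, which encodes myeloperoxidase, stood at 413 ± 91.4 TPM, Elane, neutrophil elastase, at 238 ± 48.5 and Prtn3, proteinase 3, at 182 ± 38.7.

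Other myeloid lineages were present at lower levels. Of 18 macrophage genes, 16 reached 1 TPM in both libraries. The leading members were Slc40a1, the iron exporter ferroportin, at 380 ± 95.7 TPM, the complement gene C1qb at 110 ± 35.6 and Hmox1, haem oxygenase, at 81.2 ± 27.2. All 13 megakaryocyte genes passed the threshold, with platelet factor Pf4 at 367 ± 19.7, Ppbp at 91.2 ± 9.64 and Gp1bb at 28.5 ± 3.58. Of 13 mast cell and basophil genes, 11 passed. The tryptase gene Tpsb2 stood at 518 ± 289, the chymase gene Cma1 at 350 ± 187 and the protease gene Mcpt4 at 228 ± 144, with SDs over 50 percent of the means. Of 12 dendritic and antigen presentation genes, 8 passed, led by Bst2 at 78.8 ± 16.2 and the MHC class II genes H2-Ab1 at 65.4 ± 17.7 and H2-Aa at 40.0 ± 11.3, which B cells also express. Stem and progenitor genes were above 1 TPM in 9 of 11 cases, led by Cd34 at 29.0 ± 6.59, Cd48 at 28.0 ± 4.33 and Meis1 at 22.9 ± 4.33.

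Lymphoid transcripts were sparse, and B cell genes exceeded T cell genes. The B lineage list summed to 284 ± 65.6 TPM, with 10 of 13 members at 1 TPM in both libraries, and the T lineage list to 35.1 ± 6.19 TPM, with 6 of 15. Cd74, the invariant chain of antigen presentation, stood at 145 ± 34.0, a large part of the B lineage sum, and is not limited to B cells. The B cell receptor components Cd79b and Cd79a stood at 46.2 ± 12.6 and 43.1 ± 9.65, each above the mean T lineage sum. B progenitor genes were present in 7 of 10 cases: Vpreb3 stood at 42.7 ± 9.44 and the surrogate light chain genes Igll1 and Vpreb1 at 24.1 ± 7.68 and 18.2 ± 4.72. The leading T lineage genes were Trbc2 at 7.70 ± 2.25, Lat at 7.13 ± 0.389 and Lck at 6.60 ± 0.262. Of 11 NK and innate lymphoid genes, 7 passed, led by Id2, which many other cells express, at 148 ± 31.7, then Nkg7 at 30.2 ± 8.92 and the granzyme gene Gzma at 26.9 ± 9.43.

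Antigen receptor constant regions showed an unswitched pattern of isotypes. Igkc stood at 119 ± 30.7 TPM, Ighm, the constant region of IgM, at 82.9 ± 20.5, Iglc2 at 5.76 ± 2.84 and Ighd at 5.16 ± 0.622. The switched isotypes were near or at 0: Ighg2b at 0.145 ± 0.106 TPM, Igha at 0.030 ± 0.0424, Ighg1 at 0.020 ± 0.0283, and Ighg2c, Ighg3 and Ighe with 0 counts in both libraries. Ighm was 15.9 ± 2.05 times Ighd, and Igkc 22.0 ± 5.52 times Iglc2. Of the T cell receptor constant regions matched by symbol, Trbc2 has been given above, Trbc1 stood at 3.84 ± 1.00 TPM and Trac at 1.05 ± 0.191.

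Structural cells of the spleen were represented by nearly complete lists. Stromal genes reached 1 TPM in 15 of 16 cases. The chemokine gene Cxcl12 stood at 347 ± 85.4 TPM, and the collagen genes Col3a1 and Col1a1 at 331 ± 94.2 and 228 ± 42.5. All 9 matched spleen patterning regulators were expressed, with Tcf21 at 125 ± 15.3, Nr2f2 at 31.7 ± 7.20 and Wt1 at 23.2 ± 5.66. All 13 endothelial genes passed, led by Egfl7 at 113 ± 15.8, Stab2, a scavenger receptor of sinusoidal endothelium, at 76.3 ± 8.76 and the tight junction gene Cldn5 at 55.6 ± 13.0. Smooth muscle genes passed in 6 of 8 cases, with Acta2 at 237 ± 51.3, Tagln at 81.3 ± 6.55 and Des at 17.4 ± 1.74. All 7 matched mesothelial genes passed, with Msln at 51.9 ± 2.73, Upk3b at 40.8 ± 3.34 and Krt19 at 35.9 ± 0.636.

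Genes of neighbouring organs were also measured. Of 26 pancreas genes, 22 reached 1 TPM in both libraries and the list summed to 1156 ± 796 TPM. The digestive enzyme genes Ctrb1 and Cela2a stood at 199 ± 122 and 152 ± 105, and Clps, the cofactor of pancreatic lipase, at 184 ± 132. Of 14 liver genes, 7 passed. Hp and Trf, which myeloid and other cells also express, stood at 118 ± 19.7 and 60.9 ± 12.7, and Apoa1 at 8.74 ± 4.72. Of 12 stomach and gut genes, 2 passed, and the leading members were Muc6 at 5.78 ± 0.445, Fabp1 at 2.75 ± 0.955 and Tff2 at 0.930 ± 0.721. Skeletal muscle genes passed in 3 of 8 cases, with Mylpf at 25.8 ± 0.120, Acta1 at 3.15 ± 0.962 and Myh8 at 2.75 ± 0.0354. Of 8 adipose genes, 1 passed, Fabp4 at 44.5 ± 9.28, a gene also expressed by endothelium and macrophages. Retn and Plin1 were next at 0.550 ± 0.156 and 0.030 ± 0.0424.

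Genes of response programmes were detected in both libraries. Of the immediate early and heat shock genes, 9 of 12 passed, with Hspa8 at 767 ± 30.0 TPM, Dnajb1 at 73.7 ± 4.41 and Ier2 at 33.3 ± 4.48. Hspa8 alone made up most of this list's summed 935 ± 30.5 TPM, and the median of its members was 7.46 ± 0.477. Of the interferon response genes, 10 of 12 passed, with Rsad2 at 101 ± 17.5 and Isg15 at 67.9 in replicate 1 and 94.8 in replicate 2. All 12 hypoxia and glycolysis genes passed, led by Ldha at 581 ± 7.45, Eno1 at 384 ± 10.0 and Aldoa at 226 ± 13.9. All 13 fetal and imprinted genes passed, led by Mest at 117 ± 17.7, Igf2 at 77.2 ± 11.3 and H19 at 54.2 ± 7.38. Xist, the RNA that coats the inactive X chromosome, stood at 35.4 TPM in replicate 1 and 40.9 in replicate 2. The 4 Y-linked genes Kdm5d, Uty, Ddx3y and Eif2s3y summed to 2 counts in replicate 1 and 1 count in replicate 2. The labels state that sex was not recorded.

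**Figure D1:**
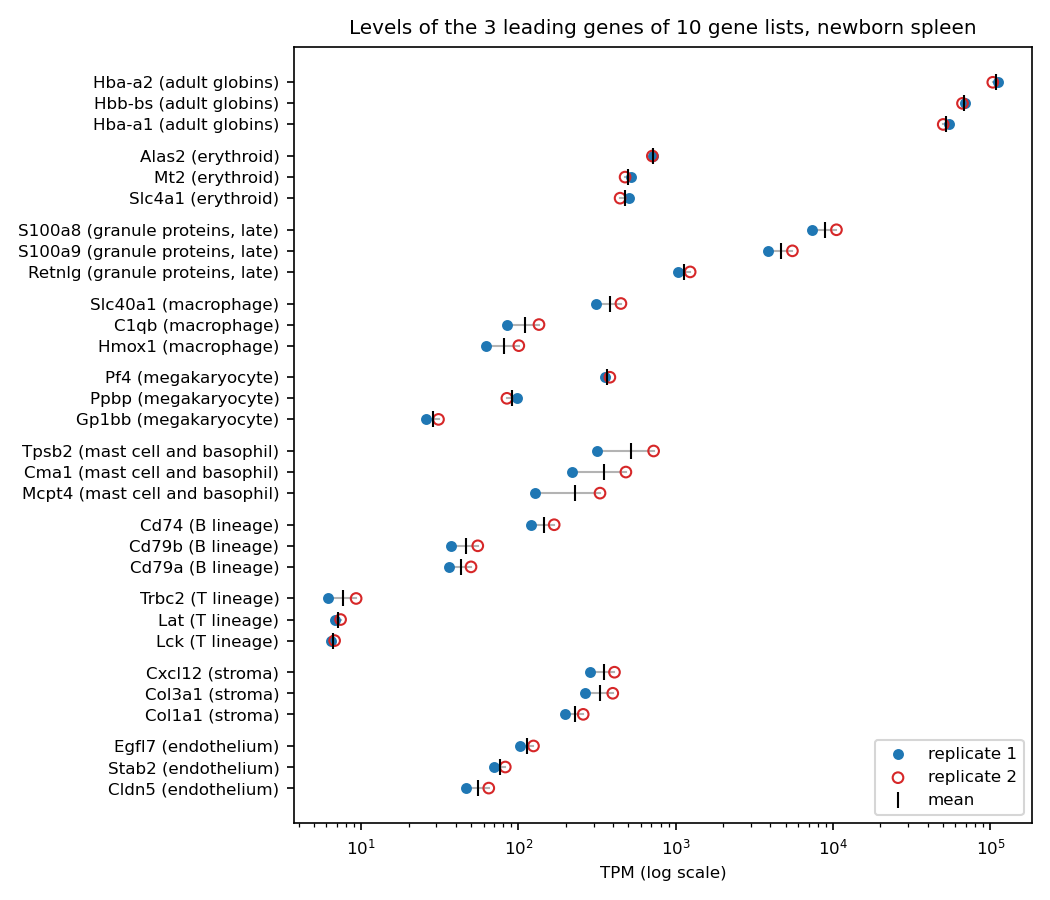
TPM of the 3 leading genes of 10 gene lists on a log scale, with a filled circle for replicate 1, an open circle for replicate 2 and a tick for the mean. Hba-a2 lies at 108047 TPM and Lck at 6.60, and the circles of the mast cell genes lie farther apart than those of the megakaryocyte genes.

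In all, 13420 of 43346 genes reached 1 TPM in both libraries. Of these, 11919 were protein-coding, 669 long noncoding, 530 pseudogenes, 164 short noncoding genes, 35 immunoglobulin or T cell receptor segments and 15 mitochondrial genes, and 88 were not in the annotation used for classes. The 20 genes with the highest mean TPM held 38.4% of TPM. After the 4 globins came Rn7s2 and Rn7s1, near-identical copies of the RNA of the signal recognition particle, at 16294 ± 1083 and 16293 ± 1083 TPM. The other members of the 20 not yet given were Gm42418 at 9897 ± 373, the histone gene Hist1h2ap at 7446 ± 1300, mt-Atp6 at 7376 ± 175, Gm28437 at 6882 ± 1020 and mt-Rnr2 at 5994 ± 323. They continued with Gpx1 at 5440 ± 469, Actb at 5359 ± 445, Gm29216 at 5049 ± 257, mt-Atp8 at 4902 ± 165, Malat1 at 4607 ± 454, Ftl1 at 4063 ± 76.7 and Gm22133 at 3971 ± 171. Gm28437 and Gm29216 are annotated pseudogenes on chromosome 1 that resemble mitochondrial genes. Gm28437 stood at 6161 and 7603 TPM in replicates 1 and 2, mt-Co3 at 2694 and 1621, and their sum at 8855 and 9224. The level of Gm28437 and the mitochondrial share thus depend on how shared reads were divided. Gm22133 (chromosome 7, 45458089 to 45458197) lies within the bounds of Ftl1 (45457944 to 45459884) and rests on 1214 and 1217 counts over 109 nt, so its TPM is inflated by a short effective length. The TPM of Malat1 (chromosome 19, 5795690 to 5802672) rests on a quantified length of 543 nt in replicate 1. That is short for its span, so its TPM may be inflated too.

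RNAs with and without poly(A) tails were both represented. Protein-coding genes outside the mitochondrial genome held 85.1% ± 0.450 of TPM, the mitochondrial genome 3.44% ± 0.00276 and short noncoding genes 3.92% ± 0.249. The list of non-polyadenylated RNAs held 3.34% ± 0.223 of TPM, nearly all of it Rn7s1 and Rn7s2, with Rn7sk at 548 ± 38.5 TPM. Its member Rn45s, the ribosomal RNA precursor, had no match by symbol, so this list's shares leave ribosomal RNA out. By share of estimated counts this list held 0.632%, the histone list 0.113% and ribosomal proteins 3.66%. The fixed list of replication-dependent histone genes, whose mRNAs lack a poly(A) tail, held 0.284% ± 0.0365 and does not include Hist1h2ap, the highest histone gene given above. Its leading members were Hist1h4d at 666 ± 73.0, Hist1h2ae at 280 ± 34.2 and Hist1h3i at 214 ± 37.1, and these genes share reads with similar copies. Ribosomal protein genes held 6.63% ± 0.153, with all 76 above 1 TPM and Rps19 at 2110 ± 22.9, Rpl32 at 1933 ± 33.9 and Rps29 at 1924 ± 111. Of the mitochondrial mRNAs, mt-Co1 stood at 2748 ± 182 TPM. The long noncoding list held 0.540% ± 0.0496, with Gas5 at 588 ± 14.7 after Malat1. Malat1 made up most of this list's summed 5405 ± 496 TPM, and by share of estimated counts the list held 0.285%.

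Transcript shares were taken for 12 genes fixed in advance, as shares of the gene's TPM. The leading transcript was Il7r-201 with 100%, the only one annotated for Il7r in the files, Pkm-201 with 96.3% ± 0.0131, Gata1-201 with 96.3% ± 0.668, Cd74-201 with 91.2% ± 0.294, Xbp1-201 with 87.1% ± 1.54 and Ighm-202 with 86.8% ± 0.561. Cd44-207 held 76.8% ± 1.21, Ikzf1-204 66.6% ± 0.715 and Fn1-202, annotated as a retained intron, 57.8% ± 3.62. Fn1-202 spans 71585526 to 71609567 on chromosome 1, only part of the 71585524 to 71653175 of the coding transcript Fn1-201. The other Fn1 reads were divided among several transcripts. The Fn1-202 share thus does not show that most Fn1 RNA kept an intron. Bcl11a-204 led with 45.1% ± 1.86, Runx1-201 with 39.6% ± 9.71 and Ptprc-203 with 33.5% ± 3.46. By estimated counts Bcl11a-204, which is 1505 nt long, held 18.5%, below Bcl11a-205 and below Bcl11a-202, which led with 46.6%. For Ptprc in replicate 1, Ptprc-201 led by counts with 42.4% against 36.1% for Ptprc-203.

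The 2 libraries were close to each other but distinct. Across 43346 genes, Pearson's r of log2(TPM + 1) was 0.994 and Spearman's rho 0.949. Genes are not independent replicates. The biological coefficient of variation, a measure of the spread between libraries beyond counting noise, was 0.128 over 15506 genes (edgeR common dispersion with an intercept-only model). The chi-square statistic of the counts was 23.6 per degree of freedom, where counting noise alone gives about 1, so they are not 1 library deposited 2 times. That they come from separate pups rests on the labels. Of the 15506 genes with a mean count of at least 20, 92.9% lay within 1.5-fold, and the median absolute log2 ratio was 0.18.

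**Figure D2:**
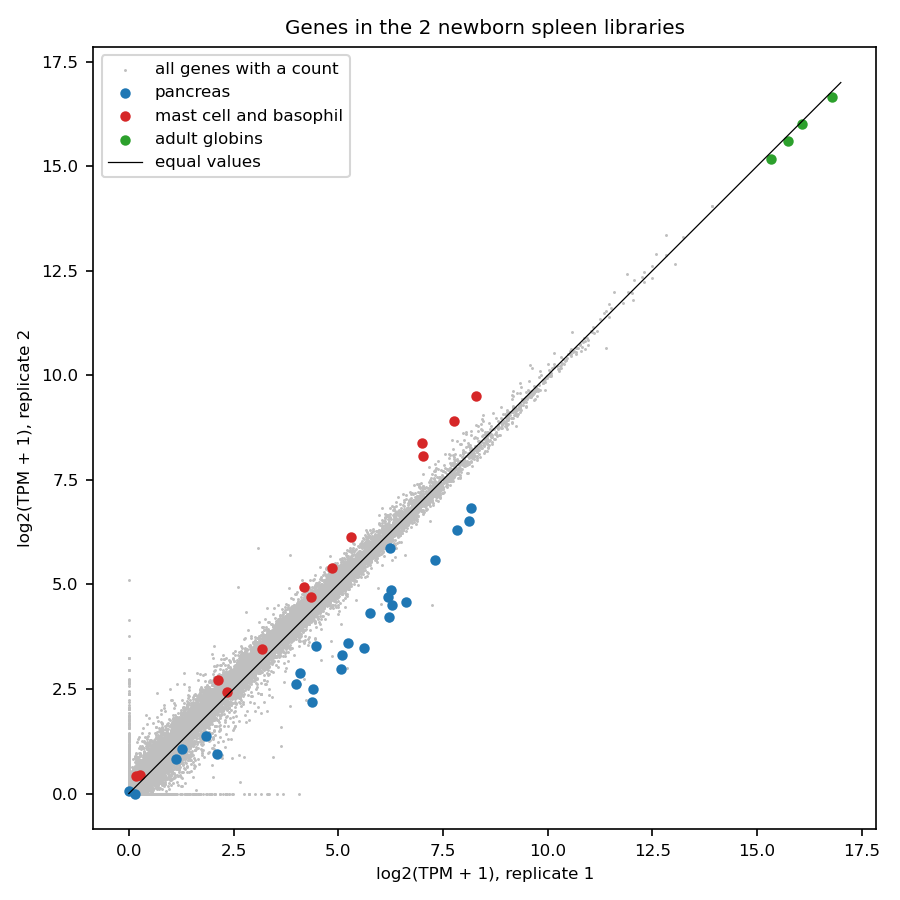
Each point is a gene with a count in either library, at log2(TPM + 1) in replicate 1 (x) and replicate 2 (y), with the pancreas, mast cell and basophil, and adult globin lists in colour and a line of equal values. Pearson's r over 43346 genes was 0.994, and most pancreas genes lie below the line and most mast cell genes above it.

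The differences that follow compare these 2 libraries, with 1 library per pup, no replicate check and no p-value across genes. Ratios are replicate 1 over replicate 2. There were 136 genes at least 2-fold higher in replicate 1 and 140 at least 2-fold higher in replicate 2. Scaled by library size alone, they were 111 and 196. Among genes with a mean count of at least 100 these counts were 49 and 23, so many of the others rested on few reads. Bracketed ranges are exact 95% Clopper-Pearson intervals of the counts and cover counting error only.

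Pancreas genes made up 9 of the 10 protein-coding genes with the largest ratios toward replicate 1. The secretory protein gene Reg1 was 6.10-fold higher (4.73 to 7.96), at 19.7 against 3.56 TPM, and the trypsin inhibitor gene Spink1 5.21-fold higher (3.99 to 6.89), at 32.4 against 6.87. The trypsin family genes Gm2663, 1810009J06Rik, Gm10334, Prss3 and Gm5771 were 12.9-fold, 10.5-fold, 5.66-fold, 5.15-fold and 4.91-fold higher. The amylase genes Amy2a2 and Amy2a3 were 7.51-fold and 4.80-fold higher. These trypsin and amylase genes have near-identical copies, and the quantification's own posterior SD for Amy2a2 in replicate 1 was 4615 on 7604 counts. The largest ratio of all belonged to Slc15a2, a peptide transporter gene (chromosome 16, 36750177 to 36784962), with 251 counts against 11, a 23.8-fold difference (13.1 to 48.2).

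Among the 10 genes with the largest ratios toward replicate 2, Cdk5rap1 (chromosome 2, 154335380 to 154373010) had 264 counts in replicate 1 and 1305 in replicate 2 and was 4.75-fold higher in replicate 2 (4.16 to 5.44). The autotaxin gene Enpp2 was 2.53-fold higher (2.21 to 2.91), the mast cell protease gene Mcpt4 2.36-fold (2.27 to 2.45), Tph1, a tryptophan hydroxylase gene, 2.36-fold (1.91 to 2.93), the macrophage receptor gene Timd4 2.27-fold (1.68 to 3.10) and the interferon-inducible gene Ifi205 2.41-fold (1.86 to 3.14). The remaining 4 were Gm4070, Gm10800, Gm14296 and Gm14391, at 5.76-fold, 3.04-fold, 2.34-fold and 2.24-fold. Posterior SDs reached 46.6 on 44.6 counts for Gm4070 and 91.4 on 104 counts for Gm14296 in replicate 1, so these values are uncertain.

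Of 34 lists with at least 3 members above the count minimum, 22 stood apart, meaning that the median log2 ratio lay outside the central 95% of 10000 random lists matched on expression. By chance 1.7 lists would if genes varied independently. Genes of a cell type can move together, so the number expected by chance may be higher. Of the 22, 7 were higher in replicate 1 and 15 in replicate 2. Some genes are in more than 1 list, such as Klf1 and Kit.

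The pancreas list lay farthest from 0. All 23 members tested were higher in replicate 1, with a median log2 ratio of 1.82, a 3.53-fold difference (percentile 100). Reg1, Prss3 and Spink1 had the largest log2 ratios, 2.57, 2.35 and 2.34. The endocrine genes Ins2 and Ins1 had smaller ones, 1.08 and 0.83. The liver list was next, with a median of 1.04 over 12 members, 9 of them higher in replicate 1 (percentile 100). With deposited TPM, compared as log2(TPM + 1), this median was 0.48, and the list's summed TPM was lower in replicate 1, 202 against 224. The fibrinogen gene Fgg, Ahsg and Apoa1 had log2 ratios of 2.01, 1.36 and 1.32 at no more than 12.1 TPM, while the 2 most abundant members, Hp and Trf, were at -0.20 and -0.30.

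Erythroid and cell division genes were modestly higher in replicate 1. All 19 erythroid genes were, with a median log2 ratio of 0.34 (percentile 100), led by Hemgn at 0.50, Rhag at 0.49 and Klf1 at 0.48. All 16 proliferation genes were too, with a median of 0.34 (percentile 100), led by Rrm2 at 0.61, Pcna at 0.48 and Birc5 at 0.44. Other genes of like abundance also leaned toward replicate 1. The random lists matched to the erythroid and proliferation lists had typical medians of 0.16 each, and 75 of 76 ribosomal protein genes were higher there. Part of each 0.34 was thus shared with genes outside these lists. Replication-dependent histones had a median of 0.40 with 43 of 45 higher in replicate 1 (percentile 100). Hist2h3c1, Hist1h2ac and Hist1h2ai led at 1.37, 0.91 and 0.85. Globin switch regulators had a median of 0.30 with 7 of 8 higher in replicate 1 (percentile 99.8). Lin28b, Klf1 and Bcl11a led them at 0.50, 0.48 and 0.47. The 4 adult globins had a median of 0.27, which did not stand apart among the matched random lists (percentile 91.8). They were the genes with the highest TPM, so nearly all genes matched to them were less abundant, and this percentile says little. Without matching, the percentile was 97.6. Smooth muscle genes had a median of 0.39 (percentile 100), but 3 of 8 were lower in replicate 1. Actg2, Cnn1 and Acta2 led at 0.75, 0.74 and 0.59. With deposited TPM, compared as log2(TPM + 1), medians were smaller, 0.19 for erythroid, 0.20 for proliferation and 0.25 for histone genes. They were 0.18 for globin switch regulators and 0.22 for smooth muscle, and these lists still stood apart.

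Mast cell and basophil genes showed the largest median toward replicate 2. Of 11 members, 10 were higher there, with a median log2 ratio of -0.66, which is a 1.58-fold difference (percentile 0). Mcpt4 and Tpsb2 had log2 ratios of -1.24 and -1.06, Cma1 stood at 218 TPM against 482, and Fcer1a was the exception at 0.04. All 18 macrophage genes were higher in replicate 2, with a median of -0.48 (percentile 0), led by Timd4 at -1.16, Cd163 at -0.61 and Adgre1 at -0.57. Late granule genes were higher in 13 of 13 cases, with a median of -0.35 (percentile 0), led by Ltf at -0.50, Lcn2 at -0.46 and Ly6g at -0.42. Early granule genes were higher in 8 of 8, with a median of -0.30 (percentile 0), led by Cebpe at -0.47, Serpinb1a at -0.43 and Mpo at -0.35. Megakaryocyte genes were near equal, with a median of -0.01 and 6 of 13 higher in replicate 1 (percentile 54.7).

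Lymphoid lists also leaned toward replicate 2. NK and innate lymphoid genes had a median of -0.52 with 8 of 8 higher in replicate 2 (percentile 0.06), led by Gzmb at -0.94, Gata3 at -0.71 and Gzma at -0.59. B lineage genes had -0.26 with 12 of 12 (percentile 0.80), led by Cd79b and Ms4a1 at -0.42 and Ebf1 at -0.38, and B progenitor genes -0.35 with 8 of 9 (percentile 1.33), led by Vpreb2 at -0.75, Rag1 at -0.63 and Igll1 at -0.48. Immunoglobulin constant genes had -0.38 with 4 of 4 (percentile 0.80, and 3.72 with no count filter, where they did not stand apart), led by Iglc2 at -0.88, Igkc at -0.39 and Ighm at -0.37. Dendritic and antigen presentation genes had -0.28 with 7 of 11 (percentile 0.625), led by H2-Eb1 at -0.50, H2-Aa at -0.45 and H2-Ab1 at -0.42, whereas Itgax at 0.52, Clec9a at 0.47 and Siglech at 0.13 were higher in replicate 1 and Zbtb46 stood at -0.09. The T lineage list, with a median of -0.38, did not stand apart (percentile 2.99), though without matching it did (percentile 0.03). Its median was -0.12 with deposited TPM (percentile 50.8) and 0.00233 at a mean count of at least 100, so its direction is not firm.

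Stromal and other lists lay on the same side. Stroma had -0.32 with 15 of 16 higher in replicate 2 (percentile 0), led by Dcn at -0.64, Postn at -0.57 and Thy1 at -0.50. The exception was the chemokine gene Ccl21a, at 52.8 TPM in replicate 1 and 20.0 in replicate 2. Spleen patterning had -0.34 with 9 of 9 (percentile 0.02), led by Nkx3-2 at -0.58, Tlx1 at -0.49 and Barx1 at -0.38. Endothelium had -0.17 with 12 of 13 (percentile 0.335, and 5.61 without matching on abundance, where it did not stand apart), led by Esam, Cldn5 and Tek at -0.35, -0.34 and -0.32. Stem and progenitor genes had -0.23 with 10 of 11 (percentile 2.08), led by Gata2 at -0.65, Hlf at -0.50 and Mycn at -0.48. Fetal and imprinted genes had -0.18 with 11 of 13 (percentile 0.26, and 4.35 without matching, so also not apart), led by Dlk1 at -0.63 and by Cdkn1c and Plagl1 at -0.35. Interferon response genes had -0.36 with 12 of 12 (percentile 0.01), led by Mx2 at -1.17, Ifit3 at -1.08 and Mx1 at -0.78.

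The remaining lists did not stand apart. Their medians were -0.09 for embryonic globins, -0.03 for mesothelium, 0.00 for immediate early genes and for long noncoding RNAs, 0.01 for non-polyadenylated RNAs, 0.03 for hypoxia and glycolysis, 0.09 for skeletal muscle, 0.11 for mitochondrial mRNAs and 0.20 for ribosomal proteins. With deposited TPM the median over all genes was -0.11 and with library size alone -0.11, against -0.01 in the main scaling, so medians within about 0.1 of 0 have no firm direction.

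**Figure D3:**
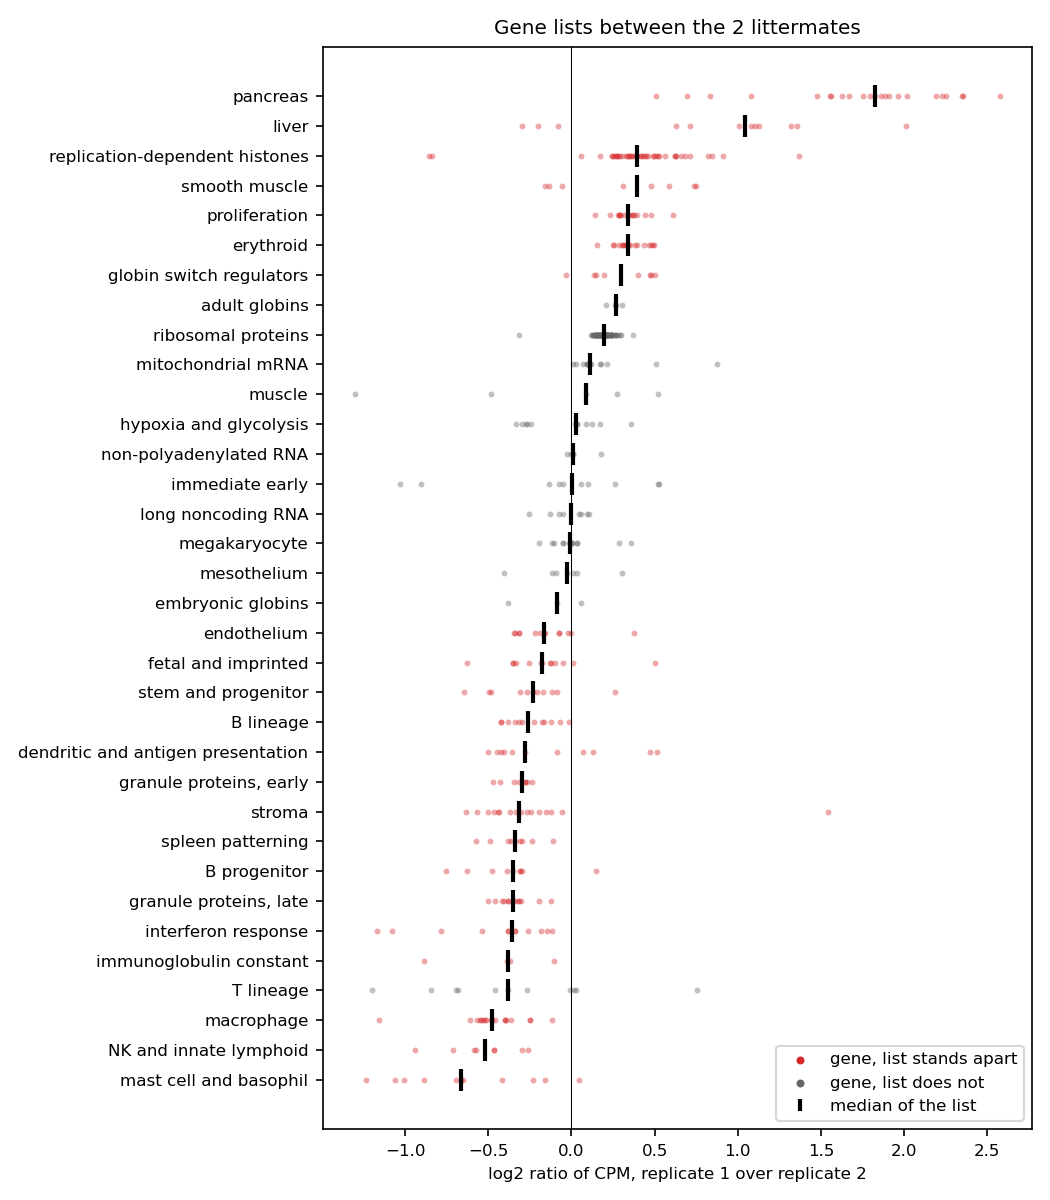
Log2 ratio of normalized counts, replicate 1 over replicate 2, for each gene (points) of 34 lists, with the list's median as a black tick and red points for the 22 lists that stood apart. The pancreas median lies at 1.82 and the mast cell and basophil median at -0.66.

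Spike-in sequences were recovered at low counts. Of 97, 22 were detected in both libraries, and 10 had at least 10 counts in both. They took 694 counts in replicate 1, or 0.00210% of the total (95% Clopper-Pearson interval 0.00194 to 0.00226), and 748 in replicate 2, or 0.00233% (0.00216 to 0.00250).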

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

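The numbered short features, which enter no comparison, received 61.5 estimated counts in replicate 1 and 82.2 in replicate 2. Both exceed the 3 counts that a count of 0 allows. In each library 9 of them were detected. What these features are is not given in the sources used here.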

How the results depend on the processing

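Removing the pancreas genes, removing adult globins from the scaling, correcting for GC content and length, and a first look with TPM and a pseudocount of 0.05 were chosen after seeing the data. No list that stood apart changed direction under the alternatives run, and 19 of 22 stood apart on the same side under each of them. A list difference cannot be run with a replicate left out. The numbers of genes 2-fold higher in replicates 1 and 2 were 51 and 37 with deposited TPM, 1267 and 1050 with no filter, 49 and 23 at a mean count of at least 100, and 44 and 48 in the first look. With a prior count of 10 they were 92 and 74. Without pancreas genes 99 of 136 remained higher in replicate 1. That drop is larger than the 26 members of the fixed pancreas list, so the genes removed went beyond that list. The adult globin share was 12.5% of counts and 31.4% of protein-coding TPM, and 25.7% to 27.8% with 1 library left out. Embryonic globins were 0.00293% of adult globins by posterior mean TPM, and 0.00202% to 0.00275% with 1 library left out. Pearson's r was 0.986 with a pseudocount of 0.1 and 0.985 over genes with a mean TPM of at least 1. Of the 38 list shares of TPM, 31 differed by more than 1 SD as shares of counts, and 18 of the 33 with a protein-coding member outside the mitochondrial genome did when rescaled to such genes; of the 12 leading transcript shares, 10 did by counts. Genes detected ranged from 9226 at 5 TPM to 18802 at 0.1 TPM, and from 13785 to 14138 in single libraries.

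Some lists crossed the percentile limits. Without matching on abundance, endothelium (median -0.17, percentile 5.61) and fetal and imprinted genes (-0.18, 4.35) no longer stood apart, while adult globins (0.27), the T lineage (-0.38) and ribosomal proteins (0.20) did. With no filter, immunoglobulin constant genes (-0.39, percentile 3.72) no longer stood apart. At a mean count of at least 100, ribosomal proteins (0.20) stood apart and the T lineage median was 0.00233. With the GC and length trend removed, the T lineage (-0.48) and long noncoding RNAs (-0.0719) stood apart, and ribosomal proteins had 0.11 (percentile 11.7). Medians of lists that had not stood apart changed sign as follows. With spike-in totals they were 0.0394 for megakaryocytes, 0.0246 for mesothelium and 0.0470 for long noncoding RNAs. With deposited TPM they were -0.0193 for skeletal muscle, -0.13 for immediate early genes, -0.13 for hypoxia and glycolysis, -0.0299 for mitochondrial mRNAs and -0.14 for non-polyadenylated RNAs. With DESeq2 size factors the immediate early median was -0.00153, and with the trend removed medians were 0.0133 for megakaryocytes, 0.0253 for mesothelium and -0.0286 for non-polyadenylated RNAs. With no filter the skeletal muscle median was -0.64 (percentile 0.15), from genes with few counts. Other causes were not tested.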

Other observations

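For the pancreas pattern the tests of shared reads and of scaling, for the mast cell pattern all tests but that of GC content and length, and for the littermate pattern the tests of counting noise and shared reads were chosen only after the result was seen. The design names no group that separates the pups.

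Pancreas transcripts were higher in replicate 1. Scaling does not account for this, since the lowest median log2 ratio over the scalings was 1.52. Reads shared between paralogs do not either: the median over 8 single-copy genes was 1.87, and the lowest was 1.56. Pancreatic tissue taken along with the spleen may explain it, as the tail of the pancreas touches the spleen: 8 acinar genes outside the fixed list had a median of 1.06, 7 of them higher in replicate 1. That median lies only just above the bound of 1 set before the test. The liver list, with a median of 1.04 (0.48 with deposited TPM), was not tested against this explanation.

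Mast cell and myeloid transcripts were higher in replicate 2. A trend with GC content or length is argued against, since the mast cell median was -0.66 before and -0.68 after its removal (percentile 0). The bound set before this test, -0.8, lay beyond the uncorrected median and was not met, so the verdict rests on the comparison before and after, chosen afterwards. A lower erythroid share raising all other lineages alike was examined with megakaryocytes as the reference. The mast cell median differed from theirs by 0.65, narrowly more than the larger interquartile range, 0.62. So these lists did not move alike. Both medians were known when the test was set, so it cannot exclude this explanation. For the granule, macrophage, B lineage and stroma lists a first test left it open, as their medians spanned 0.22, between interquartile ranges of 0.09 and 0.26. A later test was also set with the medians known. Each median differed from that of megakaryocytes by more than the larger interquartile range. The gap was smallest for B lineage, 0.25 against 0.20, and stroma, 0.31 against 0.26. These lists thus did not move alike with megakaryocytes, but a lower erythroid share as part of the cause is not excluded. Changes in the types that rose stay open. Connective tissue attached to the spleen could also contribute and cannot be told apart: the highest median was 0.39, for smooth muscle, but the spleen expresses these genes itself, skeletal muscle genes went both ways and 1 adipose gene had enough counts.

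Cdk5rap1 and Slc15a2 differed between littermates in opposite directions. Counting noise is argued against by a lower bound of 4.16 for the smaller fold. Both genes were picked for their large ratios, which this interval does not allow for. The ratio of posterior SD to count was 0 in both genes and libraries, which argues against reads divided among annotated features. It cannot exclude reads from overlapping or unannotated transcripts, since whether counting used strand is not given. In Cdk5rap1 most of the difference lay in the protein-coding transcript Cdk5rap1-201, with 249 counts in replicate 1 and 1048 in replicate 2. The retained-intron transcript Cdk5rap1-207 had 0 and 181. Cdk5rap1 is remembered as the host of an IAP retrotransposon whose methylation varies between genetically alike mice. Such an element is a candidate explanation for Cdk5rap1 only, and it rests on memory rather than on these data. Whether Slc15a2 hosts one is not certain. As a class, 13 other host genes, listed from memory, had a median absolute log2 ratio of 0.22 at percentile 63.0 of matched lists. That lies between the bounds set before the test, which leaves the candidate open. Among these hosts Eps8l1 had 93 counts in replicate 1 and 8 in replicate 2, named after its values were seen. DNA methylation was not analysed here.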
